A study of Mus musculus with 25 samples.

How the data were processed

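Counts were used as deposited. Per the submitters' processing notes, bases were called with CASAVA 1.8.2, reads were aligned to GRCm38.p6 with STAR 2.7.1a and reads per gene were counted with featureCounts 1.6.2. How the element tables were counted is not given in the sources used here beyond the labels. Per the labels, RNA was taken from whole hippocampus. The vehicle and STZ libraries were made with a KAPA stranded kit with ribosomal RNA removal and sequenced on a HiSeq2500, and the muMT and untreated wild type libraries with an Illumina TruSeq stranded mRNA kit on a NextSeq 500. The kits differ in what RNA they keep, so libraries were compared only within a table. Values are integer counts, shown as CPM, counts scaled to the normalized library size. No column of per-sample values was left out. Of 25 samples in the record 16 carry a run label, as each labelled MAVS-KO animal and wild type vehicle replicate 2 were sequenced in 2 runs, and the tables hold 1 column per animal. Which runs a column holds is not stated. Replicates are labelled animals, so p-values measure variation between animals within a table. In the muMT gene table the columns carry no replicate numbers and are numbered here in table order, and 1 untreated wild type sample has labels that name both vehicle and no treatment.

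Gene tables were read by symbol. All 55341 symbols of the muMT and labelled MAVS-KO tables were found in GENCODE M21, and 41743 of 45113 distinct symbols of the wild type STZ table, where the counts of 119 repeated symbols were added to the first entry of the same symbol. Each element table held 23420 genes and 1153 elements, and both were fitted together. Each table was fitted on its own with edgeR 4.0.16 in R 4.3.3, with low-count filtering by filterByExpr, TMM normalization, and the quasi-likelihood F test. p-values were adjusted by the Benjamini-Hochberg method over everything tested in the table, and adjusted p under 0.05 was a call. Standard errors are the absolute log2 fold change over the square root of F. The SD is between libraries. Counts were also summed by repeat class, family and 14 groups of elements chosen by name, and tested in the same fit with adjustment over these sums. Their shares of the table total were compared with an exact two-sided permutation test over all splits of the libraries. The name pattern for murine leukaemia virus like elements takes a wider set than that name.

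The 41 gene lists were tested with camera from limma 3.58.1 at its preset correlation of 0.01, with at least 3 members tested, and again with a correlation estimated from the residuals. camera sets a list against other genes. The lists were also tested with fry, which sets a list against no change. The term adjusted over the list alone means adjustment over the members of a list only. Shared calls between comparisons were set against 10000 permutations. The difference of the STZ effects was fitted on 41743 symbols that both tables share, with a group mean for each of the 4 groups. The 7 labelled MAVS-KO libraries were also split into 4 and 3 in all 35 ways. Genes were named by rule: the targeted genes, up to 12 rising and 12 falling called genes by p-value whose groups did not overlap, predicted genes left out, up to 4 called members of a list, and the 3 members with the smallest p where camera called a list with fewer called members. Where fewer than 5 genes qualified the 10 with the smallest p were added. For elements the rule took the called ones, the 5 with the smallest p where fewer than 3 qualified, and the most abundant internal part of each group. Ttr is outside the rule in wild type STZ and was chosen after its values were seen.

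Alternatives were RLE size factors, library totals alone, DESeq2 1.42.0, limma voom, no filter beyond 1 count, a mean count of at least 50, an adjusted p under 0.1, TMM on genes only for elements, a replicate block, and leaving out each library in turn. Leaving out 249 genes that vary with Ttr among untreated libraries, and taking out a trend on exon length with cameraPR, were chosen after the data were seen. Leaving out a wild type vehicle or a muMT library leaves 1 library in that group and no spread there. Calls gained or lost in those fits show only how far results depend on that library. Replicate numbers were checked as pairs by correlating deviations from group means. Same-number correlations were 0.092 and -0.061 in wild type STZ genes, 0.049, -0.028 and 0.012 in labelled MAVS-KO genes, -0.082 and 0.039 in wild type STZ elements, 0.025, -0.05 and -0.02 in labelled MAVS-KO elements, and -0.002 and -0.107 in muMT elements, so the numbers were not taken as pairs. In wild type STZ the deviations of the vehicle libraries mirror each other, as 0.092 and -0.092 against STZ replicate 1 in genes show. The same holds for the muMT libraries in the elements, so the check cannot settle pairing in these sets. No label states pairs. No paired analysis was possible for muMT genes because the columns carry no replicate numbers.

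In a self-test, negative binomial counts were drawn with the fitted means and dispersions, and 200 features were changed 2-fold or 4-fold. Of genes changed 2-fold 80%, 85% and 82% were called in the muMT, wild type STZ and labelled MAVS-KO tables, and of elements 79.4%, 1% and 97%. Of genes changed 4-fold 96%, 100% and 97% were called. Unchanged genes were 10.2%, 10.6% and 2.17% of the calls in the same order.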

Results

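Bulk RNA from whole mouse hippocampus was sequenced in 3 comparisons, which a study of endogenous retroviruses and memory set side by side. The first placed 2 muMT mice, which lack mature B cells because the immunoglobulin mu heavy chain gene is disrupted, beside 3 untreated wild type mice. The second placed 3 wild type mice that had received streptozotocin (STZ) into the cerebral ventricles beside 2 wild type mice that had received vehicle, 3 weeks after the injection. The sample labels name the vehicle arms, while the design text of the series names STZ for both injected arms, and the labels were followed. STZ is a toxin that, given by this route, is used in rodents to model sporadic Alzheimer-like disease. The third did the same in 3 STZ and 4 vehicle mice labelled MAVS-KO, in which the adaptor that relays cytosolic RNA sensing to interferon genes is targeted. Each comparison had a table of counts per gene and a table of counts per gene and repeat element. The gene table held 18104839 to 30131725 counts per library for muMT and untreated wild type, 80053392 to 89687657 for wild type vehicle and STZ, and 18002278 to 23970723 for the libraries labelled MAVS-KO. The element tables were shallower, at 778083 to 1329336, 8957267 to 17172495 and 7812833 to 9957446 counts per library in the same order.

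The targeted genes were read first. Ighm, the constant region gene of the mu heavy chain (GRCm38 chromosome 12, 113418558 to 113422730, minus strand), stood at 18.0 ± 2.5 CPM (SD, n = 3) in untreated wild type and 9.84 ± 2.01 CPM (SD, n = 2) in muMT. This is a log2 fold change of -0.88 with adjusted p = 0.263. Mavs (chromosome 2, 131234063 to 131248025, plus strand) stood at 6.40 ± 0.69 CPM (SD, n = 4) in the vehicle and 7.10 ± 0.71 CPM (SD, n = 3) in the STZ libraries labelled MAVS-KO. In wild type it stood at 8.28 ± 0.99 CPM (SD, n = 2) with vehicle and 6.35 ± 0.058 CPM (SD, n = 3) with STZ, in a table counted apart. A sum over the whole gene cannot show the loss of single exons, so neither value checks the genotype labels. The third set is called labelled MAVS-KO throughout.

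In muMT hippocampus Serpina3n, a secreted serine protease inhibitor that reactive astrocytes express, rose, and Plin4, a lipid droplet coat protein gene, fell. Serpina3n (chromosome 12, 104406729 to 104414329) went from 60.9 ± 7.7 CPM (SD, n = 3) to 289 ± 26 CPM (SD, n = 2), with a log2 fold change of 2.25 (SE 0.11, adjusted p = 5.39e-04). Plin4 (chromosome 17, 56100591 to 56109803) went from 17.9 ± 1.6 CPM (SD, n = 3) to 7.03 ± 0.25 CPM (SD, n = 2), a log2 fold change of -1.35 (SE 0.13, adjusted p = 0.04). These were the only 2 calls among 16925 genes tested with edgeR's quasi-likelihood test, and 2391 genes had an unadjusted p under 0.05. Both genes had groups that did not overlap, which chance gives in 20% of genes. Both were picked by the test on the same libraries, so this is no separate support. The genes with the next smallest p-values are given as values only. Ccn2, a matrix-associated growth factor gene, had a log2 fold change of -1.48 (adjusted p = 0.074), Pappa2, a protease of insulin-like growth factor binding proteins, -2.92 (adjusted p = 0.187), and Il33, an alarmin cytokine gene, 0.50 (adjusted p = 0.187). Serpina3m, a neighbour and close relative of Serpina3n, had 0 counts in the 3 wild type libraries and 45 counts in muMT, at least 25.6-fold higher against a floor of 3 counts over the group (adjusted p = 0.187). Reads of close relatives are not always counted apart. Other tools called more genes, with 7 by limma voom, 160 by DESeq2 (53 higher, 107 lower) and 914 with no filter on low counts. Serpina3n was called whichever library was left out. Without wild type column 1 there were 4 calls, and without wild type column 2 or 3 or muMT column 1 or 2 there was 1, Plin4 being lost. Serpina3n also varied between animals of 1 group elsewhere, from 30.2 to 161 CPM in labelled MAVS-KO vehicle.

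Ribosomal protein, myelin and MHC class I genes leaned higher in muMT, and neocortex, fibroblast and immediate early genes lower, though no list is called once a correlation among its genes is estimated. Of 41 lists fixed before the data were examined, camera placed 15 higher and 8 lower than other genes. With an estimated correlation it called 0, with 2 at an unadjusted p under 0.05. By fry, which tests each list against no change and not against other genes, 0 were called, with a smallest adjusted p of 0.352. All 50 cytosolic ribosomal protein genes had positive values, with a median log2 fold change of 0.30 (camera adjusted p = 3.13e-29; adjusted p = 0.586 with an estimated correlation). None passed the test over all genes and 48 did adjusted over the list alone. All 28 myelin and oligodendrocyte genes were positive too, among them Mag (0.57), Cnp (0.47) and Mog (0.58). In this list 13 were called adjusted over the list alone (camera adjusted p = 9.69e-19; adjusted p = 0.586 with an estimated correlation). The list of 20 genes of MHC class I presentation, the display of peptides to cytotoxic T cells, had 18 positive members, with H2-K1 at 0.54 and H2-D1 at 0.43. Of them 8 were called adjusted over the list alone (camera adjusted p = 5.08e-09; adjusted p = 0.586 with an estimated correlation). Of 39 interferon-stimulated genes 30 were positive, with Isg15 at 0.83 and Ifit3b at 0.73. Of them 5 were called adjusted over the list alone (camera adjusted p = 1.39e-06; adjusted p = 0.586 with an estimated correlation). On the lower side stood genes of meningeal and perivascular fibroblasts, with Col3a1 at -1.09 and Fmod at -1.35. Here 10 of 26 were called adjusted over the list alone (camera adjusted p = 1.13e-07; adjusted p = 0.586 with an estimated correlation). Neocortex genes were lower too, with 24 of 30 negative and 7 called adjusted over the list alone (camera adjusted p = 1.89e-08; adjusted p = 0.586 with an estimated correlation). Striatum genes were lower (camera adjusted p = 0.02; adjusted p = 0.61 with an estimated correlation), a call lost without wild type column 2 (adjusted p = 0.852) or muMT column 2 (adjusted p = 0.187). Erythrocyte genes were higher, with a median of 1.16 (camera adjusted p = 0.00399; adjusted p = 0.586 with an estimated correlation), a call lost without muMT column 2 (adjusted p = 0.814). Homeostatic microglia genes were higher in 21 of 24 (camera adjusted p = 0.00122; adjusted p = 0.586 with an estimated correlation). The immediate early genes were also lower, with Nr4a2 at -0.98 and 2 of 30 called adjusted over the list alone (camera adjusted p = 4.51e-06; adjusted p = 0.586 with an estimated correlation). B cell and immunoglobulin genes, the cell type muMT mice lack, had only 5 of 24 members measured well enough to test, and the list was not called (camera adjusted p = 0.65). Choroid plexus genes were called higher (camera adjusted p = 0.0181; adjusted p = 0.768 with an estimated correlation), but wild type column 1 held 25 CPM of the choroid plexus marker Ttr against 6620 and 6070 CPM in columns 2 and 3. Without that column the list lay lower (camera adjusted p = 1.89e-19), and without muMT column 2 its call was lost (camera adjusted p = 0.0646).

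Repeat elements differed little between muMT and wild type. Of 797 elements tested 3 rose and 0 fell. Tigger8, a fossil DNA transposon, rose from 163 ± 5 CPM (SD, n = 3) to 330 ± 64 CPM (SD, n = 2) with a log2 fold change of 1.01 (SE 0.16, adjusted p = 0.008). X6B_LINE, an old LINE fragment, rose by 0.55 (adjusted p = 0.00895) and MLT1A1, an old LTR element, by 0.35 (adjusted p = 0.0455). Their groups did not overlap, which chance gives in 20% of elements. As these 3 were picked by the test on the same libraries, this is no separate support. Adjusted over the elements alone 4 were higher and 4 lower, and 93 had an unadjusted p under 0.05. With TMM scaling, the B1 SINE elements rose by 0.07 on the log2 scale (adjusted p = 0.00959) and the TcMar-Tigger family by 0.17 (adjusted p = 0.0232). The young L1 elements, which include copies still able to move, had a log2 fold change of -0.235 (adjusted p = 0.031). Shares of all counts in the table are another measure, which this fit did not test. They were 15.1 ± 0.12% (SD, n = 3) and 15.3 ± 0.088% (SD, n = 2) for B1, 1.23 ± 0.026% and 1.33 ± 0.06% for TcMar-Tigger, and 0.594 ± 0.051% and 0.487 ± 0.016% for young L1. An exact two-sided permutation test of the shares gave p = 0.2 for B1 and for young L1 and p = 0.1, the smallest possible, for TcMar-Tigger. For the SINE class the share was 32.8% and 32.5% while its log2 fold change was 0.04 (adjusted p = 0.0702), so the sign depends on the scaling. These 3 and the Alu family, which holds nearly the same elements as the B1 group, were the 4 of 56 classes, families and groups that passed. Intracisternal A particles, an active endogenous retrovirus group, held 0.148 ± 0.0042% and 0.128 ± 0.015% and were not called with TMM scaling (adjusted p = 0.367). The counts moved with the library left out. There were 0 elements without wild type replicate 1 or 4, 17 without wild type replicate 3 and 38 without muMT replicate 3. There were 0 groups without wild type replicate 4 and 1 without muMT replicate 1. The fall of young L1 was not called without wild type replicate 1 or 4 or muMT replicate 3. With normalization on genes only, 3 elements were higher and 3 lower, and of the groups 0 were higher and 1 lower. In the 3 element tables the 500 most abundant genes had a median of 0.0713%, 0.0277% and 0.0655% of their gene table counts. Of the 200 highest gene entries 172, 177 and 176 had an expressed gene on the opposite strand, against 31, 38 and 44 of 200 random entries. The gene entries of these tables therefore hold mostly reads on the strand opposite to the annotation. Element entries were not checked this way. If they were counted alike, element values in all 3 comparisons reflect reads opposite to the annotated strand of the elements.

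In wild type mice STZ hippocampus held far less RNA of choroid plexus genes, the secretory epithelium of the ventricles, than vehicle hippocampus. Enpp2, the gene of autotaxin (chromosome 15, 54838901 to 54952892), fell from 1597 ± 487 CPM (SD, n = 2) to 154 ± 19 CPM (SD, n = 3), a log2 fold change of -3.38 (SE 0.19, adjusted p = 0.00191). Kl, the gene of the ageing-related hormone klotho (chromosome 5, 150952607 to 150993817), fell from 173 ± 34 CPM (SD, n = 2) to 27.3 ± 4.9 CPM (SD, n = 3), a log2 fold change of -2.66 (SE 0.16, adjusted p = 0.002). Col8a1, a collagen gene, and Cldn2, a tight junction claudin, fell with log2 fold changes of -3.17 and -4.57 (adjusted p = 0.00191 each). Otx2, a transcription factor of this epithelium, and Prlr, the prolactin receptor, fell with log2 fold changes of -3.50 and -3.32 (adjusted p = 0.002 each). Ttr, the transthyretin gene and most abundant choroid plexus transcript, stood at 1730 and 2780 CPM with vehicle and 17.5, 8.0 and 76.2 CPM with STZ. edgeR called 146 of 21256 genes, all lower with STZ, and 1341 had an unadjusted p under 0.05. All 146 had groups that did not overlap, which chance gives in 20% of genes. As the test on the same libraries picked them, this is no separate support. Of the 27 choroid plexus genes 24 fell, and all 27 did adjusted over the list alone, with a median log2 fold change of -3.54 (adjusted p = 0.108 by camera with an estimated correlation, and 0.125 by fry). Another list also holds 2 of the 27 genes, and 17 had at least 1 CPM in every STZ library. Of 23 ependymal genes, which serve the cilia of the ventricle lining, 3 fell and 14 did adjusted over the list alone (camera adjusted p = 1.63e-22; adjusted p = 0.752 with an estimated correlation). The 3 were Dnah6 (-1.54), Rsph1 (-1.03) and Cfap43 (-1.23), which all lost their call without vehicle replicate 2 or STZ replicate 1 or 2, and the last 2 also without vehicle replicate 1. Igf2, an insulin-like growth factor, and Igfbp2, one of its binding proteins, fell by 1.61 and 1.49 on the log2 scale. Their list of insulin and glucose handling was not called (camera adjusted p = 0.32). Like the other falling genes, Igf2 and Igfbp2 could reflect choroid plexus tissue carried along at dissection, which was not tested for them alone. Both lost their call without STZ replicate 1 or 2, and Igfbp2 also without vehicle replicate 2. DESeq2 called 393 genes (28 higher, 365 lower), limma voom 127 and edgeR with no filter 217. Fits without a vehicle replicate left 1 vehicle library and no spread among vehicle animals, so calls lost there are hard to read. Without STZ replicates 1, 2 and 3 there were 35, 51 and 311 calls (38 of the last higher). With 249 genes that vary with Ttr among untreated libraries left out, an alternative chosen after seeing the data, there were 30. Of the 146 calls 74 were themselves left out. Slc4a2, which stayed, had a log2 fold change of -1.68 in both fits, while its adjusted p went from 0.00543 to 0.0296. The drop therefore does not show how many falls depend on genes that vary with Ttr.

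**Figure D1:**
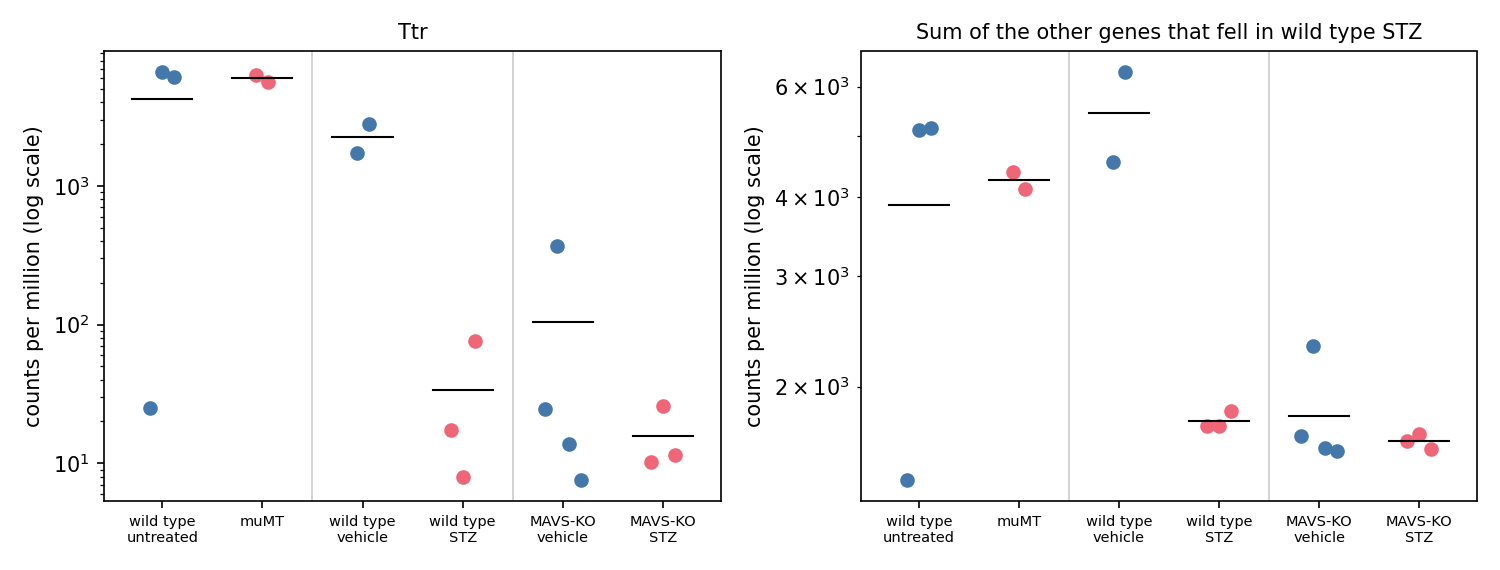
CPM (log scale) of Ttr on the left and summed over the other genes that fell in wild type STZ on the right, for the 17 libraries in 6 groups; points are libraries and bars group means. Ttr lies at 1730 and 2780 CPM in wild type vehicle and at 8.0 to 76.2 CPM in wild type STZ, and 1 untreated wild type library holds 25 CPM beside 6620 and 6070 CPM.

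No gene rose in wild type STZ by the main test over all genes, while DESeq2 found 28 higher, limma voom 0 and edgeR with a replicate block 112. Interferon-stimulated genes, the targets of antiviral signalling, ranked high as a list, as did several lists of immune cells and glia. Of 48 tested 46 were positive, with a median log2 fold change of 0.89, and 10 were called adjusted over the list alone (camera adjusted p = 2.01e-23; adjusted p = 0.752 with an estimated correlation). Among them Ifit3 stood at 5.01 ± 0.59 CPM (SD, n = 2) with vehicle and 11.9 ± 3.2 CPM (SD, n = 3) with STZ (adjusted p = 0.111). Irf7, a master regulator of interferon genes, had a log2 fold change of 2.01 (adjusted p = 0.157) and Rtp4 one of 1.17 (adjusted p = 0.178). Of 24 homeostatic microglia genes 23 were positive, with 0 called adjusted over the list alone (camera adjusted p = 4.66e-08; adjusted p = 0.752 with an estimated correlation). Of 20 genes of MHC class I presentation 18 were positive (camera adjusted p = 3.2e-05; adjusted p = 0.752 with an estimated correlation). The 35 inflammatory cytokine and NF-kB genes tested, with Cxcl10 at 3.77 (adjusted p = 0.252), were called by camera (adjusted p = 4.65e-07; adjusted p = 0.752 with an estimated correlation), but not without STZ replicate 3 (adjusted p = 0.248). Genes of MHC class II presentation were positive in 10 of 10 (camera adjusted p = 5.81e-04; adjusted p = 0.752 with an estimated correlation), of T and NK cells in 8 of 8 (camera adjusted p = 0.00196; adjusted p = 0.752 with an estimated correlation) and of neutrophils and monocytes in 6 of 7 (camera adjusted p = 0.00297; adjusted p = 0.752 with an estimated correlation). All 3 lost their call without STZ replicate 3 (adjusted p = 0.179, 0.49 and 0.352), and MHC class II also without vehicle replicate 1 (adjusted p = 0.0902). Of 36 genes of reactive astrocytes 28 were positive (camera adjusted p = 4.56e-06; adjusted p = 0.752 with an estimated correlation), a call lost without vehicle replicate 1 (adjusted p = 0.0779). STZ replicate 3 stood apart in C3, a complement gene, at 42.5 CPM against 2.91 and 6.12 CPM in the other STZ and 1.22 and 2.72 CPM in the vehicle libraries. The list of disease-associated microglia was called higher (camera adjusted p = 7.09e-04; adjusted p = 0.753 with an estimated correlation). It lost both call and direction without STZ replicate 3 (adjusted p = 0.393). It also lost the call without vehicle replicate 1 (adjusted p = 0.0786). Myelin genes were lower, with 26 of 28 negative and 3 called adjusted over the list alone (camera adjusted p = 9.3e-15; adjusted p = 0.218 with an estimated correlation). The 1 that fell over all genes was Enpp2, which the choroid plexus list holds too. In all, camera called 13 lists higher and 5 lower, and with an estimated correlation 0, with 2 at an unadjusted p under 0.05.

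Repeat elements in wild type STZ gave no calls that could be told from the spread of the vehicle libraries. The limit on strand given for muMT holds here too. edgeR called 0 of 1117 elements over the table and 0 adjusted over the elements alone, 2 had an unadjusted p under 0.05, and DESeq2 and limma voom called 0 each. The internal part of VL30, an endogenous retrovirus, showed this spread. MMVL30-int had 1902 and 13660 CPM in the vehicle libraries and 2744 ± 150 CPM (SD, n = 3) with STZ (adjusted p = 0.641). Vehicle replicate 2 had a table total of 8957267 counts, of which 91.003% were element counts against 94.994% to 95.124% elsewhere. This animal was sequenced in 2 runs, and which of them the column holds is not stated. Its counts lay at a chi-square of 137 to 148 per degree of freedom from those of every other library, and the others lay at 2.46 to 3.56 from each other. Intracisternal A particles took 0.525 ± 0.022% (SD, n = 2) of the table with vehicle and 0.523 ± 0.0047% (SD, n = 3) with STZ, and LINE elements 26.7 ± 3.3% and 29.3 ± 0.22%. None of the 56 classes, families and groups was called by edgeR, and 0 had an unadjusted p under 0.05. Fits without vehicle replicate 1 or 2 left 1 vehicle library and so no spread among vehicle animals, and their calls are not given. On simulated counts with the spread fitted to all libraries of the table, the test found 1% of elements changed 2-fold. It found 54% of those changed 4-fold, so 2-fold changes could hardly be detected here.

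In mice labelled MAVS-KO, STZ hippocampus had more RNA of single genes of stress responses and neuronal activity, such as Cdkn1a, Hspa5 and Fos, and less of the mitochondrially encoded mt-Cytb and mt-Nd5. Cdkn1a, the p21 cell cycle inhibitor induced by p53 (chromosome 17, 29090976 to 29100727), rose from 2.74 ± 0.53 CPM (SD, n = 4) to 8.90 ± 1.59 CPM (SD, n = 3), a log2 fold change of 1.69 (SE 0.18, adjusted p = 0.00637). Hspa5, the endoplasmic reticulum chaperone BiP (chromosome 2, 34771970 to 34777547), rose from 164 ± 8 CPM (SD, n = 4) to 255 ± 19 CPM (SD, n = 3), by 0.64 (SE 0.06, adjusted p = 0.00426). Fos, an immediate early transcription factor (chromosome 12, 85473890 to 85477273), rose from 5.43 ± 3.06 CPM to 21.8 ± 0.45 CPM, by 2.02 (SE 0.28, adjusted p = 0.0294). The mitochondrial cytochrome b gene mt-Cytb fell from 4409 ± 157 CPM to 3486 ± 140 CPM, a log2 fold change of -0.34 (adjusted p = 0.0292). Slc5a3, a myo-inositol transporter, rose by 0.48 (adjusted p = 0.00426), Stxbp2, a syntaxin binding protein of granule release, by 0.75 (adjusted p = 0.00426) and Zmym1 by 0.62 (adjusted p = 0.00426). The clock output genes Dbp and Ciart fell by 0.42 and 0.73 on the log2 scale, and the cold-inducible RNA binding protein gene Cirbp fell by 0.44. Zfp125 fell by 2.72 on the log2 scale (adjusted p = 0.0219). Zfp125 overlaps other called genes and Slc5a3 lies inside Mrps6, which was called too (0.55, adjusted p = 0.0424), and counts of overlapping genes are uncertain. edgeR called 51 of 22746 genes, 30 higher and 21 lower, and 2658 had an unadjusted p under 0.05. All 51 had groups that did not overlap, which chance gives in 5.71% of genes. The 51 were picked by the test on the same libraries, so this is no separate support. limma voom called 46 genes, DESeq2 190 (96 higher, 94 lower) and edgeR with no filter 195. Slc5a3, Hspa5, Stxbp2, Zmym1 and Cdkn1a were called whichever library was left out. The counts were 26, 20, 15 and 27 without vehicle replicates 1, 2, 3 and 4, and 16 and 8 without STZ replicates 1 and 3. Fos, Ciart and Cirbp kept their call for 1 of the 7 libraries left out, mt-Cytb and Dbp for 2 and Zfp125 for 4, and all but Zfp125 lost it without STZ replicate 3.

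Among the lists in labelled MAVS-KO the immediate early genes, which neurons switch on with activity, had the smallest camera p. Among them Fos, Arc (0.98, from 84.6 ± 14.8 to 166 ± 31 CPM, adjusted p = 0.0299) and Sik1 (0.66, adjusted p = 0.0483) rose. Of 30 tested these were 3, and 19 did adjusted over the list alone (camera adjusted p = 1.18e-21; adjusted p = 0.0844 with an estimated correlation; 0.043 by fry). All 13 genes of the mitochondrially encoded list were negative, and 2 of them fell, mt-Cytb and mt-Nd5 (-0.32). Adjusted over the list alone 9 fell (camera adjusted p = 7.45e-20, 0.0844 with an estimated correlation and 0.0219 by fry). The mitochondrial gene mt-Ta, outside this list, fell too (-0.66, edgeR adjusted p = 0.0346), a call kept for 1 of 7 libraries left out. Of 39 genes of oxidative stress and the unfolded protein response 4 rose and 12 did adjusted over the list alone (camera adjusted p = 9.47e-10; adjusted p = 0.0844 with an estimated correlation; 0.0219 by fry). The 4 were the chaperone genes Hspa5, Dnajb1 (0.45), Pdia4 (0.38) and Hspa1b (0.75). In the p53 and DNA damage list Cdkn1a alone rose over all genes and 7 of 31 did adjusted over the list alone (camera adjusted p = 0.0016; adjusted p = 0.0874 with an estimated correlation; 0.0219 by fry). Of 18 CA1 neuron genes 1 fell, Wfs1 (-0.36, adjusted p = 0.0219), and 3 did adjusted over the list alone (camera adjusted p = 0.00146; adjusted p = 0.178 with an estimated correlation; 0.043 by fry). Striatum genes were higher too, with 4 of 19 called adjusted over the list alone (camera adjusted p = 0.00921; adjusted p = 0.627 with an estimated correlation), a call lost without STZ replicate 3 (adjusted p = 0.228). Ependymal genes were higher (camera adjusted p = 0.00187; adjusted p = 0.627 with an estimated correlation), a call lost without STZ replicate 2 (adjusted p = 0.347). The interferon-stimulated genes, downstream of MAVS, had 36 of 42 positive members and 0 called adjusted over the list alone (camera adjusted p = 0.00555; adjusted p = 0.756 with an estimated correlation). Without STZ replicate 2 the list turned lower (adjusted p = 0.819), and it lost its call without vehicle replicates 1 and 4 (adjusted p = 0.168 and 0.136). Choroid plexus genes were lower (camera adjusted p = 0.0053; adjusted p = 0.756 with an estimated correlation), with Ttr at 369 CPM in vehicle replicate 2 and 7.56 to 24.6 CPM in the other vehicle libraries. Without that library the direction turned (adjusted p = 0.346), and without STZ replicate 3 the call was lost (adjusted p = 0.0701). With a library left out, Dnajb1 kept its call in 4 of 7 cases, Pdia4 in 3, Arc and Wfs1 in 2, and Sik1, Hspa1b and mt-Nd5 in 1, and all lost it without STZ replicate 3. In all, camera called 12 lists higher and 9 lower, and with an estimated correlation 0, with 5 at an unadjusted p under 0.05.

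**Figure D2:**
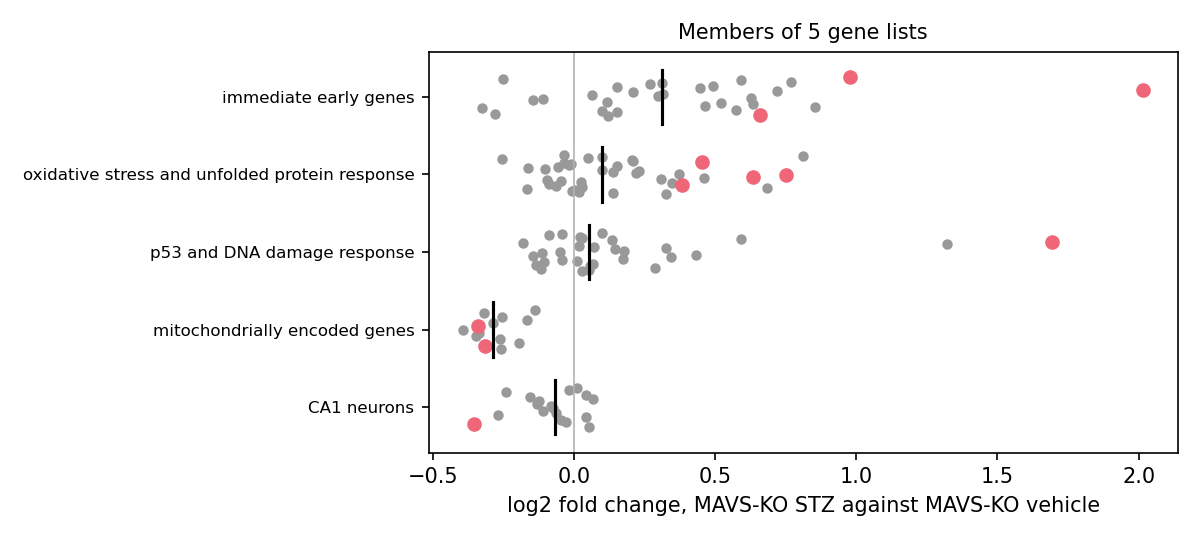
Log2 fold change of each member of 5 gene lists in labelled MAVS-KO STZ against vehicle; red points have adjusted p under 0.05 over all genes and black bars are list medians. The medians are 0.31 for the 30 immediate early genes and -0.29 for the 13 listed mitochondrially encoded genes.

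Repeat elements in labelled MAVS-KO moved by small amounts, and the limit on strand given for muMT applies to them as well. With TMM scaling the SINE class, short elements copied from small RNAs, rose by 0.03 on the log2 scale (adjusted p = 0.0212), and its B1 and B2 groups by 0.04 each (adjusted p = 0.0212 and 0.025), and young L1 elements fell (log2 fold change -0.05, adjusted p = 0.025). As shares of the table, which that fit did not test, the SINE class held 35.2 ± 0.48% (SD, n = 4) and 35.9 ± 0.15% (SD, n = 3), B1 12.3 ± 0.21% and 12.7 ± 0.092%, B2 8.69 ± 0.13% and 8.92 ± 0.068%, and young L1 3.82 ± 0.046% and 3.67 ± 0.052%. The exact two-sided permutation p of the shares was 0.0571 for the SINE class and for both groups and 0.0286, the smallest possible, for young L1. These were called among 6 of the 56 classes, families and groups, the Alu and B2 families repeating the B1 and B2 groups. None was called without vehicle replicate 4 or STZ replicate 1, 3 were called without STZ replicate 2, and 0 with the total of genes alone. The fall of young L1 was not called without vehicle replicate 1, 2 or 4 or STZ replicate 1 or 3. Intracisternal A particles held 0.523 ± 0.012% and 0.521 ± 0.009% (adjusted p = 0.999 with TMM scaling), and their internal part IAPEz-int 3265 ± 77 and 3281 ± 68 CPM. edgeR called 0 of 1106 single elements over the table and 0 adjusted over the elements alone, with 113 at an unadjusted p under 0.05; DESeq2 called 4 and limma voom 2. The smallest p belonged to MurERV4-int, an endogenous retrovirus (log2 fold change 0.16, adjusted p = 0.0857), and to L1Md_Gf, a young L1 (-0.20, adjusted p = 0.0857), and 1 element was called without STZ replicate 2. On simulated counts the test found 97% of elements changed 2-fold.

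**Figure D3:**
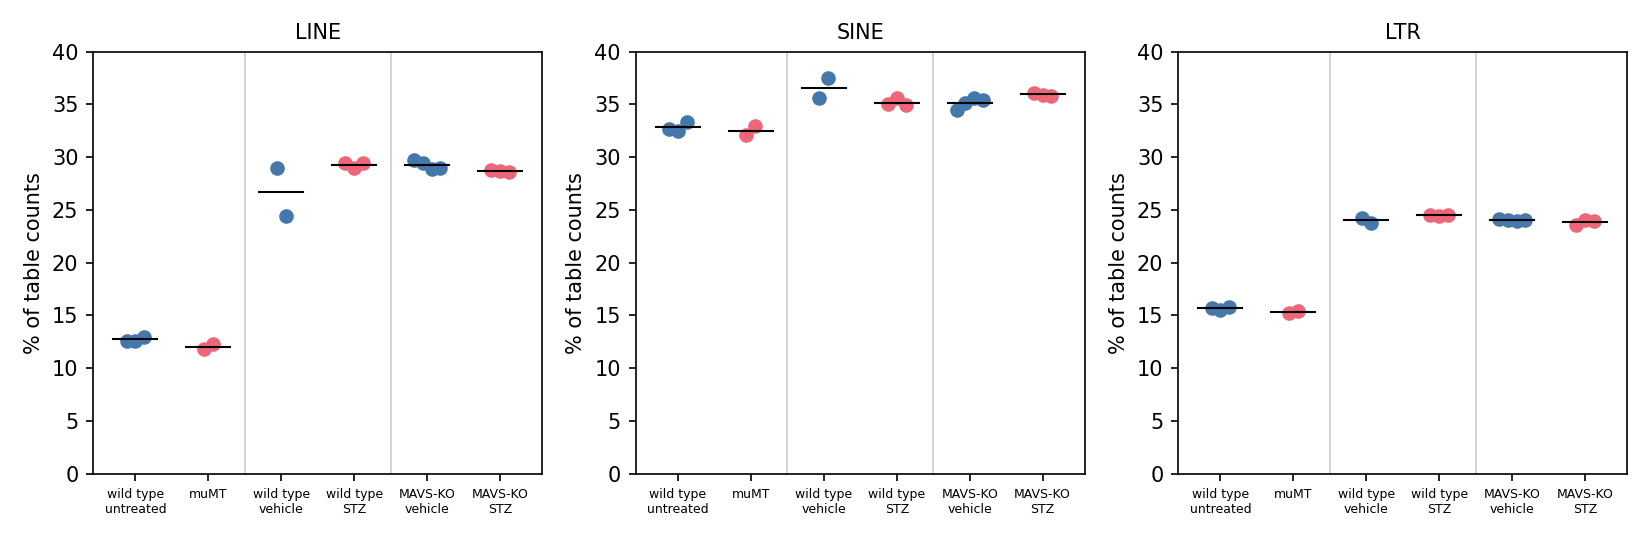
Percent of element table counts taken by LINE, SINE and LTR elements in each library of the 6 groups; points are libraries and bars group means. LINE elements take 12% to 12.7% on average in the muMT table and 26.7% to 29.3% in the STZ tables, which came from another library kit, and 1 wild type vehicle library lies at 24.4%.

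The effects of STZ in wild type and in labelled MAVS-KO were set against each other over 20379 genes. edgeR's interaction term called 85, with 75 more negative and 10 more positive in wild type, and 2041 had an unadjusted p under 0.05. Of the 85 genes 54 were among those that fell in wild type, such as the glucose transporter gene Slc2a12 (difference -2.37, adjusted p = 0.00436), Kl (-2.26, adjusted p = 0.0219) and Prlr (-3.34, adjusted p = 0.0231). Another 11 were among the calls in labelled MAVS-KO, such as Stxbp2 (-0.81, adjusted p = 0.00436). The vehicle libraries labelled MAVS-KO held little choroid plexus RNA to begin with, with Ttr at 7.56 to 369 CPM. Genotype was confounded with strain, sequencing and a table counted apart. DESeq2 called 231 genes. By edgeR 26, 45 and 141 were called without wild type vehicle replicate 2 and STZ replicates 1 and 3, and 160, 55, 46 and 45 without the labelled MAVS-KO vehicle replicates 2 and 4 and STZ replicates 1 and 2. No gene was called by edgeR in more than 1 of the 3 comparisons, for any of the 3 pairs. As 10000 permutations of gene labels gave means of 0.0163, 0.0053 and 0.282 shared genes, these absences do not tell shared from distinct responses. Across genes, which are not independent replicates, Spearman's rho of the fold changes was -0.18 for muMT and wild type STZ, 0.04 for muMT and labelled MAVS-KO STZ, and -0.02 for both STZ effects.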

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

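The checks of single libraries and of the difference of STZ effects were fixed before their values were computed, as were those of RNA quality, of gene length over all called lists and of the splits of libraries. The tests on choroid plexus tissue, on the Ighm region, on neighbouring genes and on parts of the called lists were chosen after the results had been seen.

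In the labelled MAVS-KO vehicle group, 5 of 81 named genes had a single library far from the rest by Dixon's Q test. Chance would give about 1 in 20 if genes varied independently, so the number alone is near that of chance. Ttr, Ace and Aqp1 stood apart in the same library, vehicle replicate 2, so the count does not speak against an outlying library. Only this group, the only one with 4 libraries, was tested. Single libraries also stood apart in smaller groups, as Ttr at 25 CPM beside 6620 and 6070 CPM in untreated wild type. In vehicle replicate 2 the choroid plexus genes Ttr, Ace and Aqp1 had 370, 37.3 and 4.46 CPM, against 7.59 to 24.6, 15 to 18.4 and 0.558 to 0.893 CPM in the others. Banp had 19.2 CPM in replicate 4 against 21.3 to 21.5, and Cirbp 64 CPM in replicate 3 against 58.4 to 59.3.

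The STZ effect differed between wild type and labelled MAVS-KO in 12 of 136 tests of named genes by edgeR's interaction term. It was more negative in wild type for Slc2a12 (-2.37, adjusted p = 0.00436), Slc28a3 (-4.368, adjusted p = 0.00612), Cfap43 (-1.639, adjusted p = 0.00941), Slco1c1 (-0.97, adjusted p = 0.00974) and Col4a3 (-2.445, adjusted p = 0.0173). The same held for Kl (-2.256, adjusted p = 0.0219), Prlr (-3.345, adjusted p = 0.0231) and Cd59a (-2.143, adjusted p = 0.0318), of which Kl and Prlr are on the choroid plexus list, Cfap43 on the ependymal, Slco1c1 on the endothelial and Cd59a on the complement list. For Cd59a the difference joins a fall in wild type (-0.96, adjusted p = 0.0268) and a value of 1.18 in labelled MAVS-KO that is not called (adjusted p = 0.197). Genes that rose in labelled MAVS-KO differed too, namely Stxbp2 (-0.813, adjusted p = 0.00436), Zmym1 (-0.569, adjusted p = 0.0241) and Dlx1 (-0.661, adjusted p = 0.033), and Zfp125, which fell there, differed by 2.763 (adjusted p = 0.0201). None of the 12 can be read as an effect of genotype, which was confounded with strain, sequencing and table. For Kl and Prlr the labelled MAVS-KO vehicle libraries also held little choroid plexus RNA to lose, with Ttr at 369 CPM or less. Slc2a12, Slc28a3, Col4a3, Cfap43, Slco1c1 and Cd59a fell in wild type too, and the same limit could hold for them, which was not tested. Slc28a3 did not pass the low-count filter in the fit of labelled MAVS-KO alone, so no effect is given for it there.

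The fall of choroid plexus genes in wild type STZ has at least 2 readings. If tissue carried along at dissection varies from sample to sample, the falling genes should vary together in untreated mice, and 99.3% of 139 measured ones were lowest in the untreated library with the lowest Ttr. This is consistent with carry-over and shows that such differences arise without STZ. If STZ acts on the choroid plexus itself, the genes might fall in labelled MAVS-KO as well, where their median log2 fold change was -0.12 over 111 genes, but with so little choroid plexus RNA in those vehicle libraries this test cannot tell. Damage by STZ to an epithelium that lines the injected ventricle therefore stays open.

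Short genes, such as those of ribosomal proteins, and long genes, such as those of ion channels, stood apart in muMT, which a trend on gene length between libraries could also give. The list calls are weak to begin with, as with an estimated correlation 0 of 23 are called. After the trend on exon length was taken out with cameraPR, a ranked form of camera, 17 of 23 lists kept call and direction, which lies between the bounds set in advance and cannot tell. By cameraPR 8 lists stayed at adjusted p under 0.001, among them ribosomal proteins (4.95e-19), myelin (2.15e-14) and MHC class I presentation (1.87e-07). These 8 were picked by that outcome, and none is called with an estimated correlation even before the trend is taken out. They therefore cannot show whether the trend is the whole cause. The 9 lists near the threshold, such as ion channels (0.0407), and 6 that lost their call leave it open too. RNA quality or library make-up may still differ between animals, as the slope on length ranged over 0.067 among untreated wild type libraries, near the difference of -0.07 between the groups.

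Near Ighm, the locus targeted in muMT, 6 genes within 15 Mb had p under 0.001 where 0.639 were expected (permutation p = 1e-04, the smallest possible; at most 2 in 95% of draws), among them Serpina3n and Serpina3m. As 3 of the 6 are Serpina3 relatives, these genes were then left out, which gave 3 genes (permutation p = 0.0218). None of these 3, Crip1, Itgb8 and Tmem196, was called by edgeR (adjusted p = 0.187 to 0.263). Itgb8 and Tmem196 lie within 1 Mb of each other, and the permutation p can be too small where neighbouring genes vary together. Donor chromosome carried along with the mutation could thus contribute to the Serpina3n change, and neither this nor the lack of B cells was excluded. In labelled MAVS-KO 14 called genes had a called neighbour within 1 Mb (permutation p = 4e-04; at most 8 in 95% of draws), which might point to haplotypes that differ among animals. Once overlapping genes were merged and mitochondrial genes left out, a step added after the first value was seen, there were 6 (permutation p = 0.231), so that reading stays open.

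Splits of the 7 labelled MAVS-KO libraries into 4 and 3 bear on chance. For genes, 1 of 35 splits, the real one, gave 51 calls and the highest other gave 15. This is the smallest share that 35 splits allow, so chance is unlikely but not excluded. The splits cannot tell STZ from other differences between the arms. For gene lists called by camera at the preset correlation, 5 of 35 splits gave as many as the real 21 calls. Every other split called lists too, from 6 to 22 of them. Calls by fry were not counted in the splits, which do not bear on them. For retroelement groups 3 gave as many as the real 6 (highest other 6). Chance can therefore not be excluded for camera list calls or for groups. For elements the real split gave 0 calls, so all 35 gave as many whatever the data (highest other 2). The splits therefore tell nothing about elements.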

How the results depend on the processing

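Settings were fixed before the values were seen, except the Ttr and gene length alternatives. Of 148 settings run on 13 counts of calls, 83 left the count within 1.5-fold and 65 moved it. Some moves follow from the setting itself, as a looser threshold can only add calls and the Ttr alternative left out 74 called genes. For the others the cause was not tested.

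For muMT genes the 2 calls became 160 with DESeq2, 7 with limma voom and 914 without a filter, and 1 to 4 with a library left out. The 3 muMT elements became 12 without a filter, 1 at a mean count of at least 50, 6 with TMM on genes only, 0 with a replicate block and 7 at adjusted p under 0.1, and 0 to 38 with a library left out. The 4 muMT groups became 1 with the genes-only total and 0 with a block, and 0 to 4 with a library left out.

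For wild type STZ genes the 146 calls became 393 with DESeq2, 489 with a block (112 higher, 377 lower) and 30 with the Ttr alternative, and 27 to 311 with a library left out. Elements stayed at 0 except with a library left out, at 0 to 1058, and groups likewise at 0 to 55.

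For labelled MAVS-KO genes the 51 calls became 190 with DESeq2, 195 without a filter, 15 with a block and 117 at adjusted p under 0.1, and 8 to 37 with a library left out. The 0 elements became 1 with library totals alone, 4 with DESeq2, 2 with limma voom, 14 without a filter, 1 with a block and 4 at adjusted p under 0.1, and 0 to 1 with a library left out. The 6 groups became 0 with the genes-only total and stayed at 6 with a block, and 0 to 8 with a library left out.

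Gene lists called by camera went to 0 with an estimated correlation in all 3 comparisons. With a library left out they numbered 16 to 23, 12 to 21 and 14 to 22 for muMT, wild type STZ and labelled MAVS-KO, with a block 18 and 17 for the last 2, and 19 for muMT without the length trend and 19 for wild type STZ with the Ttr alternative. Direction turned in 7 cases. The ranges given are over libraries left out. In muMT these were choroid plexus (adjusted p from 1.89e-19, turned, to 0.0646) and ependymal cells (2.39e-05 to 0.105, turned), both turned without wild type column 1. In wild type STZ it was disease-associated microglia with a block (adjusted p = 0.424) and without STZ replicate 3 (range 3.15e-11 to 0.393). In labelled MAVS-KO it was MHC class I presentation (1.5e-06 to 0.887) and interferon-stimulated genes (1.61e-07 to 0.819), both turned without STZ replicate 2, and choroid plexus (2.51e-06 to 0.346), turned without vehicle replicate 2.

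The 85 differences of STZ effects became 140 without a filter, 231 with DESeq2 and 74 with a block, and 26 to 160 with a library left out. Using only 1 of the 2 runs was not run for labelled MAVS-KO or for wild type vehicle replicate 2, because the tables hold 1 column per animal.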
